A study of Mus musculus with 2 samples.

How the data were processed

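Single-cell 5' RNA libraries were analysed from optic nerves of Nf1-OPG mice, 1 library per treatment, each from the nerves of 10 mice at 12 weeks of age. The deposited values are UMI counts per gene and barcode, made with Cell Ranger 8.0.0 for the anti-PD-1 library and 8.0.1 for the anti-TIGIT library per the file headers, and aligned to mm10 per the submitters' processing notes. Those notes also name Seurat 5.0.3 and R 4.1.1, whose results were not used here. Each file covers 32285 genes, and 21912 barcodes were given in all.

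Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs, which left out 39 and 89 barcodes (anti-PD-1 and anti-TIGIT) under the first limit and 121 and 186 over the second. Doublets were scored with Scrublet per library. Its automatic threshold was used in both, with an expected rate of 0.8% per 1000 cells, and removed 684 and 155 cells. The 20666 retained cells had median depths of 4475 and 4117 UMIs. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without T cell receptor, immunoglobulin, mitochondrial, ribosomal protein and sex-linked genes, gave 30 components and a graph of 15 neighbours, and both libraries were clustered together without batch integration by the Leiden method at resolution 1.0. This gave 39 clusters, and T and NK cells clustered again gave 16. Clusters were named by marker genes fixed before the data were examined, and left unnamed where the markers did not decide.

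Classes with at least 100 cells in each library were compared, 12 in all. Counts were summed per class and library and given as CPM of the class, with exact Poisson intervals and the log2 ratio of anti-PD-1 over anti-TIGIT with its exact conditional binomial interval. Where a library held 0 counts, the ratio against a floor of 3 counts is given with the lower limit of the exact interval. Shares have exact Clopper-Pearson intervals, and a share of 0 is given with its exact upper limit. All intervals are at 95% and cover counting error only. With 1 library per group, neither tests nor p-values nor standard errors were computed. Where the median ratio over all genes lay more than 0.1 log2 from 0, values were also taken relative to that median.

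Of 222 genes in 22 lists fixed beforehand, 3 (Mx1, Clec7a and Aldoa) were missing from the files. Each list was summarised by the median log2 ratio of (CPM + 5) over its genes with at least 10 counts, an interval from 1000 Poisson draws, and its percentile among 10000 random lists matched in 20 expression bins. Genes were named by size: the 12 largest log2 ratios of (CPM + 5) in each direction in CD8 T cells, and 5 in each other class, among genes with at least 50 counts and a UMI in at least 5% of the cells of a library. Mitochondrial, ribosomal protein, haemoglobin, receptor and immunoglobulin segment, sex-linked and unnamed predicted genes were left out, as were genes below 25% of the highest CPM of another class, which can be free RNA. Genes of the lists were not filtered in this way. Receptor-positive shares were taken after thinning each cell to 1000 UMIs. Cells were called by sex from Xist and 4 Y-linked genes.

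The calculation was tested on simulated data, in which counts were drawn by a Poisson law from the CD8 T cell profile of both libraries together, at each library's depth, and 200 genes were given known ratios. Intervals covered the true ratio for 96.1% of 8200 genes, 85.1% of genes changed by a log2 ratio of 1.5 and 98.1% of those changed by 2 were found past 2-fold in the right direction, and 1 of 8104 unchanged genes passed that size. A raised list lay at percentile 100 and an unchanged list at 47.8. The draws followed the Poisson law that the intervals assume, so the coverage checks the calculation only. Spread between cells or mice was not simulated, and the intervals do not cover it.

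Alternatives planned before the data were seen were no doublet removal, limits of 500 genes with 5% mitochondrial UMIs or of 20%, resolutions of 0.5 and 2.0, CD8 T cells gated by UMIs, scaling by the median ratio, thinning to 1000 UMIs before summing, minimum counts of 1 and 200, pseudocounts of 1 and 20 CPM, thinning to 500 or 2000 UMIs or none, and no filter for free RNA. Added after the data were seen were Xist-positive cells only, cells with Y-linked transcripts only, the Ly6c2/Gzmk cluster only, and T and NK cells clustered without list genes. Where an alternative clustered the cells anew, each cluster took the main name of most of its cells. Expression in classes under 100 cells in either library was left out, and the values of some single genes are not reported here.

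Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.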

Results

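Optic nerves of Nf1-OPG mice, a mouse model of the optic pathway glioma that arises in neurofibromatosis, were profiled by droplet single-cell RNA sequencing. The nerves of 10 mice, all 12 weeks old, were pooled for each library, and live cells were sorted by their exclusion of 7-AAD, a dye that enters dead cells. In the first group the mice were given an antibody against PD-1, the product of Pdcd1, and in the second an antibody against TIGIT, the product of Tigit. Both receptors restrain T cells and are carried by exhausted CD8 T cells, and the comparison asks how the cells of the nerve differed between the treatments. No untreated library was analysed here, so each value sets the treatments against each other. The labels name the optic nerve as the tissue, although their protocol also mentions suspensions of meningeal dura, and they do not say whether any dura entered these libraries.

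The anti-PD-1 library held 13997 barcodes and 85031565 UMIs, with a median of 4505 UMIs and 1795 genes per barcode. The anti-TIGIT library held 7915 barcodes and 40733655 UMIs, with a median of 4082 UMIs and 1660 genes. After filtering, 13169 and 7497 cells were retained. There are no replicates: each group has 1 library, so each difference has no replicate check and no test was run. Intervals in parentheses are 95% intervals and cover counting error only. The libraries also carried different Cell Ranger versions (8.0.0 for anti-PD-1 and 8.0.1 for anti-TIGIT), which cannot be told apart from the treatment.

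The retained cells were mostly immune cells and glia, and their makeup differed between the libraries. Border macrophages, the macrophages of the meninges and vessels, made up 5.63% (5.24 to 6.03) of retained cells in the anti-PD-1 library and 16.6% (15.8 to 17.5) in the anti-TIGIT library. Oligodendrocytes, which form myelin, made up 15.5% (14.9 to 16.2) and 25.5% (24.5 to 26.5), and cDC2, dendritic cells that present antigen to CD4 T cells, 3.57% (3.26 to 3.90) and 8.14% (7.53 to 8.78). Microglia went the other way, at 8.90% (8.42 to 9.40) and 4.79% (4.32 to 5.30), as did oligodendrocyte precursor cells (OPCs) at 5.35% (4.98 to 5.75) and 1.57% (1.30 to 1.88). Regulatory T cells, which carry Foxp3 and restrain immune responses, made up 4.34% (4.002 to 4.71) and 1.64% (1.37 to 1.95). The size of some of these differences depended on the sex of the cells. The difference for oligodendrocytes was -9.94 points over all, -19.8 among Xist-positive cells and -5.23 among cells with Y-linked transcripts, that for microglia 4.11, 2.80 and 8.29, and that for OPCs 3.78, 2.96 and 5.90. For regulatory T cells it was 2.70, 2.73 and 3.37. For cDC2 it was -4.57 over all and -5.92 among cells with Y-linked transcripts, and among Xist-positive cells -1.23, with an interval holding 0 (-2.72 to 0.143).

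CD8 T cells made up 10.1% (9.59 to 10.6) of the anti-PD-1 library and 7.76% (7.17 to 8.39) of the anti-TIGIT library, a difference of 2.34 percentage points (1.53 to 3.13). That difference depended on how the cells were taken. It was 0.210 points at a clustering resolution of 0.5 and 5.12 points with CD8 T cells gated by UMIs. Among cells with Y-linked transcripts it was 0.513 points (-0.905 to 1.90), and among Xist-positive cells 8.19 points.

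Smaller classes included plasma cells at 4.53% (4.18 to 4.90) and 3.21% (2.83 to 3.64), fibroblasts at 3.47% (3.16 to 3.80) and 2.64% (2.29 to 3.03), B cells at 1.64% (1.43 to 1.87) and 2.15% (1.83 to 2.50) and NK cells at 0.790% (0.646 to 0.956) and 1.81% (1.52 to 2.14). The directions for plasma and B cells turned among cells with Y-linked transcripts, at differences of -0.179 (-1.33 to 0.941) and 0.0523 points (-0.825 to 0.897), and that for B cells also among Xist-positive cells, at 0.400 points (-0.293 to 0.994), but these intervals hold 0. The fibroblast difference was 0.829 points over all, 1.86 among Xist-positive cells and 1.82 among cells with Y-linked transcripts. Plasma cells made up 4.38% and 0.468% of Xist-positive cells, a difference of 3.92 points (3.06 to 4.75) against 1.32 over all, and the NK cell difference there had an interval holding 0 (-1.18 to 0.139). Neutrophils numbered 6 and 44 cells, and mast cells or basophils 8 and 28. Clusters left unnamed held 18.9% (18.3 to 19.6) and 7.71% (7.12 to 8.34) of retained cells, and unnamed T cell clusters 5.71% (5.32 to 6.12) and 8.07% (7.46 to 8.71). Several unnamed clusters leaned to anti-PD-1: the largest held 1145 and 170 cells, another 452 and 6, and another 150 and 0 of 7497, which allows a share of up to 0.0492%. Their median depths of 1082, 1340 and 1249 UMIs were low, a sign of poor quality. The largest had C1qa, C1qb, C1qc, Trem2 and Cxcl13 among its 10 leading genes. C1qa, C1qb and Cxcl13 were also high in microglia and border macrophages. The shares of those 2 classes therefore depend on leaving this cluster unnamed. Another unnamed cluster leaned to anti-TIGIT, with 13 and 45 cells. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

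**Figure D1:**
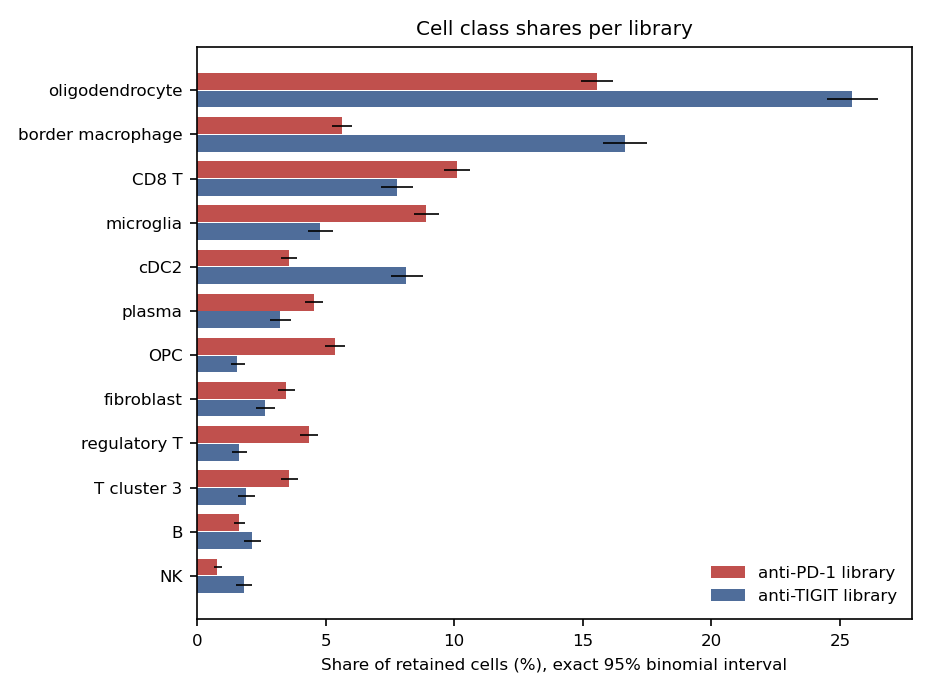
Share of retained cells, in percent, of the 12 cell classes compared between the libraries, with a bar per library and exact 95% binomial intervals. Border macrophages reached 16.6% in the anti-TIGIT library against 5.63% in the anti-PD-1 library, and microglia 4.79% against 8.90%.

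In CD8 T cells, genes of inhibitory receptors were higher in the anti-PD-1 library, the targets of both antibodies among them. Pdcd1 (ENSMUSG00000026285) stood at 860 CPM (UMIs of the gene per 1000000 UMIs of the class) against 252, a log2 ratio of 1.77 (1.64 to 1.91), and Tigit at 688 against 267, a log2 ratio of 1.37 (1.23 to 1.502). Lag3 and Havcr2, receptors of exhausted T cells, had log2 ratios of 1.85 (1.65 to 2.05) and 1.65 (1.20 to 2.13), and Ctla4 1.42 (1.27 to 1.57). Of the 10 inhibitory receptor genes measured, 9 were higher, none was lower, and the interval of Btla held 0 (-0.97 to 0.05). The list's median log2 ratio was 1.02 (0.89 to 1.27), at percentile 100 of 10000 random lists matched on expression. Tox, a transcription factor that maintains exhaustion, stood at 765 against 390 CPM (0.97, 0.86 to 1.09). Of 13 exhaustion programme genes 8 were higher, among them Tox2 (2.03) and Batf (1.38), 1 was lower (Eomes, -0.42) and 4 had an interval holding 0. Their median was 0.55 (0.28 to 0.64).

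Some genes of progenitor, memory and circulating T cells were lower in the same cells. Tcf7, the transcription factor of progenitor and memory T cells, stood at 90.3 against 136 CPM (-0.59, -0.81 to -0.37), Lef1 at a log2 ratio of -1.09 and Klf2, which keeps T cells in circulation, at -1.01. Of 13 genes of that list 6 were lower, 1 was higher (Ccr7, 0.49) and 6 had an interval holding 0, with a median of -0.40 (-0.46 to -0.08). Among 12 cytotoxic effector genes 6 were lower and 4 higher. Granzyme genes Gzma (61.7 against 200 CPM, -1.70) and Gzmm (-2.57) were lower, as were Klrg1 (-2.16) and Klrk1 (-1.11), while Klrd1 (0.87), Cst7 (0.67), Nkg7 (0.59) and Prf1 (0.46) were higher. That list's median was -0.16 (-0.26 to -0.07).

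Chemokines for monocytes and T cells were higher as well, with Ccl3 at 335 against 84.3 CPM (1.99, 1.76 to 2.23) and Ccl4 at 1054 against 519 (1.02). Of 10 effector cytokine and chemokine genes 6 were higher, 1 was lower (Il2, -1.02) and 3 had an interval holding 0 (Tnf, 0.21), for a median of 0.35 (0.23 to 0.53). Costimulatory receptors Tnfrsf9 (600 against 219 CPM, 1.45) and Tnfrsf4 (1.39) led the activation and costimulation list, of whose 10 genes 6 were higher and 2 lower (Cd40lg, -0.79, and Cd226, -0.32), with a median of 0.42 (0.26 to 0.52). Tissue residency genes split, with 4 of 7 higher (Cxcr6, 0.62, and Itgae, 0.60) and 3 lower (Itga1, -1.31), around a median of 0.21 (0.11 to 0.31). Of 10 T cell receptor complex genes 8 were higher and 1 lower (Lat, -0.20), with a median of 0.35 (0.28 to 0.48). Some of these genes, such as Cd3e and Cd3g, also served to name the class.

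These values moved with the mix of CD8 T cell clusters. Within the Ly6c2/Gzmk cluster alone, the inhibitory receptor median was 0.46 (0.21 to 0.73), Pdcd1 had a log2 ratio of 1.22 and Tigit 0.68. There the direction turned for the exhaustion programme (-0.0307), the progenitor and memory list (0.0831), the cytokine and chemokine list (-0.30), tissue residency (-0.16) and Ccl3 (-0.37). Within Xist-positive CD8 T cells, of which the anti-TIGIT library held 65, all in that cluster, the inhibitory receptor median was 2.28, that of the exhaustion programme 1.51 and Pdcd1 4.39. Within cells with Y-linked transcripts the inhibitory receptor median was 1.06.

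**Figure D2:**
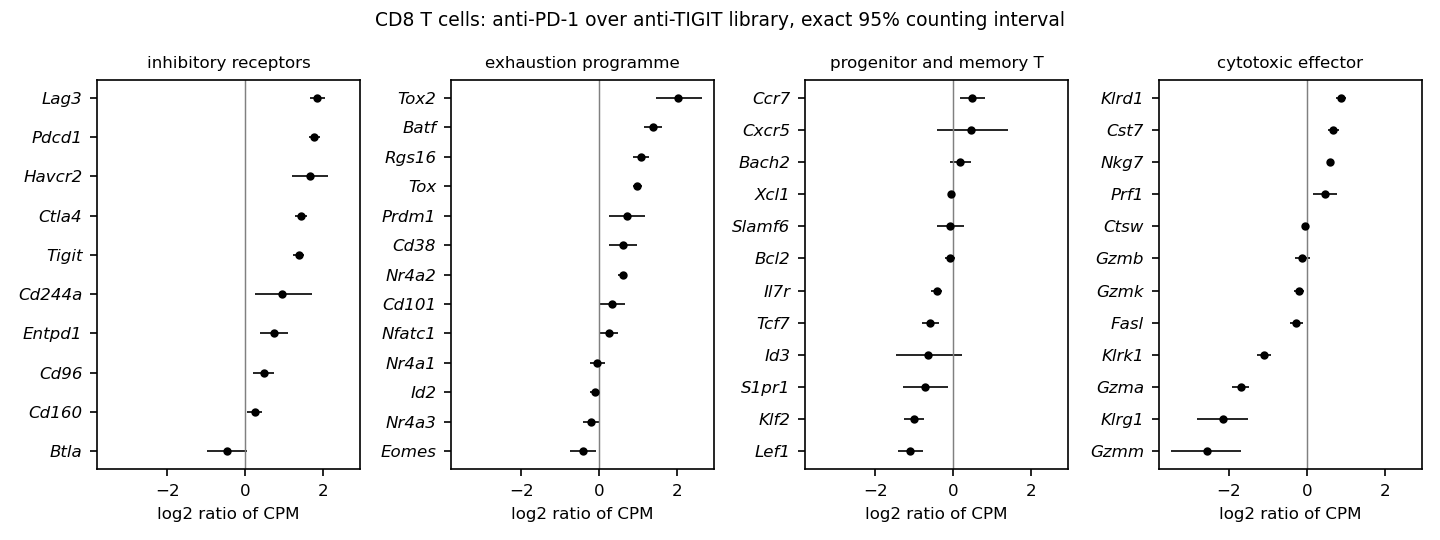
Log2 ratio of CPM, anti-PD-1 over anti-TIGIT, in CD8 T cells for genes of the inhibitory receptor, exhaustion programme, progenitor and memory, and cytotoxic effector lists, with exact 95% counting intervals as bars. Pdcd1 lies at 1.77 and Tigit at 1.37, while Tcf7 lies at -0.59 and Gzma, which can be free RNA, at -1.70.

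By size alone, over 5559850 and 1933299 UMIs of CD8 T cells, 112 of 8304 genes (1.35%) were at least 2-fold higher in the anti-PD-1 library on the scale of log2(CPM + 5) and 29 (0.349%) at least 2-fold lower. The 12 largest ratios upward belonged to Tff1 (ENSMUSG00000024032), Sdcbp2, Ccl3, Nrn1, Lag3 (ENSMUSG00000030124), Pdcd1, Tox2, Ccrl2, Adgrg1, Spock2, Ccr8 and Pawr. Tff1, a secreted trefoil peptide of mucous epithelia, stood at 49.8 against 2.07 CPM (4.59, 3.22 to 6.48), Ccr8, a chemokine receptor of T cells in skin and tumours, at 159 against 49.1 CPM (1.69, 1.39 to 2.01), and Nrn1 at 245 against 63.1 CPM (1.95, 1.69 to 2.23). The 12 largest downward belonged to Tmtc2, Klf3, Klrg1, Ifi208, Tob1, Il12rb2, St3gal6, Gpr183, Itga1, Btbd11, Filip1l and Amd1. Tmtc2 was lower in 11 of the 12 compared classes and Filip1l in all 12, so neither is particular to CD8 T cells. Klrg1, a receptor of short-lived effector cells, stood at 6.12 against 27.4 CPM (-2.16, -2.83 to -1.52), Klf3 at 29.3 against 98.3 (-1.75) and Il12rb2, a chain of the interleukin 12 receptor, at 20.1 against 57.4 (-1.51). Without the filter for free RNA, 8 and 10 of these were still named. Counts by size depended on the settings: within the Ly6c2/Gzmk cluster 10 genes were higher and 14 lower, with the UMI gate 371 and 48, with a pseudocount of 20 CPM 31 and 8, and with a pseudocount of 1 CPM 210 and 58. Among Xist-positive cells 492 genes were higher and 85 lower, and with at least 200 counts 54 and 15. Spock2, at 2.80 (1.53 to 4.45), lay at -0.0857 among Xist-positive cells.

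The share of CD8 T cells in which each receptor was seen differed as well. With every cell thinned to 1000 UMIs, Pdcd1 was detected in 51.3% (48.5 to 54.0) of 1297 CD8 T cells of the anti-PD-1 library and in 14.9% (12.1 to 18.04) of 572 in the anti-TIGIT library, and Tigit in 45.5% (42.7 to 48.2) and 18.01% (14.9 to 21.4). Ctla4 was detected in 38.6% and 15.7%, Lag3 in 29.4% and 7.87%, Havcr2 in 5.55% and 1.57%, and Tox in 42.3% and 18.2%. Unthinned, these shares were 74.7% and 26.8% for Pdcd1, 76.2% and 39.3% for Tigit, 67.3% and 28.2% for Ctla4, 56.1% and 16.2% for Lag3, 17.97% and 4.12% for Havcr2 and 70.7% and 32.8% for Tox. CD8 T cells had median depths of 3698.5 and 2901.5 UMIs, and 33 and 10 were too shallow to thin. In oligodendrocytes, which should lack these receptors and had median depths of 7590.5 and 6340.5 UMIs, the thinned share was 0.245% for Pdcd1 in the anti-PD-1 library and 0 of 1904 cells in the anti-TIGIT library, which allows a share of up to 0.194%. Tigit was seen in 0.393% and 0.105% of oligodendrocytes and Tox in 1.33% and 1.79%. The Pdcd1 difference was 36.4 points (32.2 to 40.4) at 1000 UMIs and 23.3 points at 500 UMIs. In Xist-positive cells Pdcd1 was detected in 56.0% and 4.62% of CD8 T cells, and in cells with Y-linked transcripts in 45.1% and 17.6%. In the latter the Havcr2 difference was 2.86 points, with an interval holding 0 (-0.909 to 6.35). Within the Ly6c2/Gzmk cluster the differences for Pdcd1 and Tigit were 9.97 and 5.30 points.

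**Figure D3:**
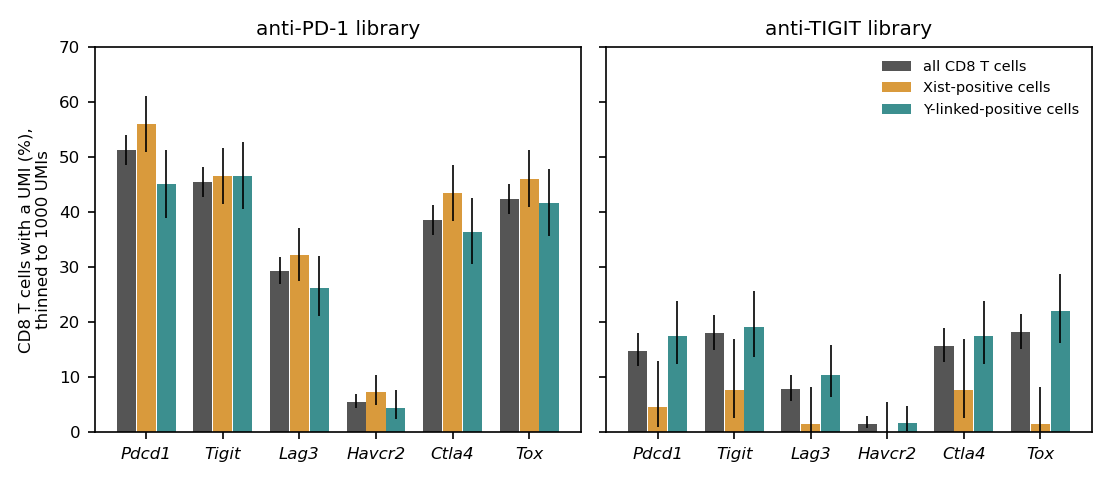
Percent of CD8 T cells with at least 1 UMI of Pdcd1, Tigit, Lag3, Havcr2, Ctla4 and Tox after thinning each cell to 1000 UMIs, per library, over all cells, Xist-positive cells and cells with Y-linked transcripts, with exact 95% binomial intervals. Pdcd1 was detected in 51.3% of cells of the anti-PD-1 library and 14.9% of the anti-TIGIT library.

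CD8 T cells fell into 3 clusters, and the libraries lay mostly in different clusters. The exhausted-like cluster held 45.4% (42.7 to 48.1) of CD8 T cells of the anti-PD-1 library (604 of 1330) and 7.56% (5.55 to 10.0) of the anti-TIGIT library (44 of 582). The cluster named Ly6c2/Gzmk, in which Gzmk led and Ly6c2 was not among the 10 leading genes, held 32.2% (29.7 to 34.8) and 83.5% (80.2 to 86.4), and the cluster with Xcl1 and Crtam among its leading genes 22.4% (20.2 to 24.7) and 8.93% (6.74 to 11.6). Because the exhausted-like cluster is defined by genes that differed between the libraries, T and NK cells were also clustered without 74 genes of 7 T cell lists. The clusters that took over the exhausted-like name then held 47.6% (44.8 to 50.4) of 1244 and 8.75% (6.47 to 11.5) of 526 CD8 T cells. Each new cluster took the earlier name of most of its cells. The new shares are thus tied to the earlier clusters and are no independent check of them. The Ly6c2/Gzmk share was 30.1% (27.6 to 32.8) and 82.5% (79.0 to 85.7). Among cells with Y-linked transcripts the exhausted-like difference was 30.2 points and among Xist-positive cells 55.2, against 37.9 over all.

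Interferon, cell cycle and other lists were also measured in CD8 T cells. Of 15 interferon gamma response and MHC genes 11 were higher and 2 lower (B2m, -0.18, and H2-D1, -0.10), with a median of 0.25 (0.15 to 0.38). Type I interferon response genes had a median of 0.18 (0.03 to 0.29), with 2 of 10 higher (Ifit3, 0.56), and that median turned to -0.29 with the UMI gate, -0.14 without doublet removal and -0.12 at a resolution of 0.5. Among 6 checkpoint ligand genes 4 were higher, with Cd274 at 0.77 and a median of 0.66 (0.34 to 0.78). Cell cycle genes had a median of -0.07 (-0.21 to 0.14) with 2 of 12 higher (Birc5, 3.43, and Mki67, 0.94), and glycolysis and hypoxia genes 0.21 with 3 of 8 higher and 1 lower. Dissociation stress genes, which respond to handling, had a median of -0.04 (-0.11 to 0.15) with 5 of 13 higher and 3 lower. Markers of other cells also moved in CD8 T cells, where they are read as free RNA: the myelin gene Mbp stood at 2399 against 1545 CPM, the microglial gene C1qa at 27.9 against 9.31, Cd74, the invariant chain of class II MHC and a member of the interferon gamma list, at 271 against 104 and the plasma cell gene Jchain at 349 against 191. Among lists of other cells, 2 of 8 myelin genes were higher (median 0.21), 5 of 11 activated microglia genes higher and 2 lower (0.39), 1 of 6 homeostatic microglia genes higher and 1 lower (-0.05), 2 of 8 myeloid inflammation genes higher (0.16) and 1 of 4 reactive astroglia genes lower (0.13). Of 7 glioma-supporting signal genes 3 were higher (among them Cxcl13, 1.86, which can be free RNA from microglia) and 2 lower (Ccr2, -1.02), for a median of 0.48 (0.05 to 0.50), and 1 of 4 haemoglobin genes was lower (-0.15). In the Ly6c2/Gzmk cluster the medians of the glioma-supporting and activated microglia lists turned to -0.12 and -0.19, and among Xist-positive cells that of myelin turned to -0.13.

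Oligodendrocytes of the anti-PD-1 library carried far more transcripts of the interferon gamma response and of antigen presentation. All 16 genes of that list were higher, with a median log2 ratio of 2.79 (2.72 to 2.82). B2m, the light chain of class I MHC, stood at 1397 against 232 CPM (2.59), the class I genes H2-K1 at 1042 against 98.6 (3.40) and H2-D1 at a log2 ratio of 3.03, and the peptide transporter gene Tap1 at 4.14. Of 11 type I interferon response genes 10 were higher, among them Isg15 (79.2 against 4.17 CPM, 4.25) and Ifit3 (2.71), with a median of 2.38 (2.23 to 2.49). Cd274, which encodes the PD-1 ligand PD-L1, stood at 96.8 against 4.45 CPM (4.44, 4.08 to 4.83). The largest ratios upward were those of the interferon-induced GTPases Ifi47 (6.31), Iigp1 (5.02), Gbp2 (8.57) and Tgtp2 (5.06) and of H2-T23 (4.28), and downward those of Ldb3 (-1.96), Filip1l (-1.29), Zc3h7a (-0.78), Jarid2 (-0.80) and Sorcs3 (-0.87). Over 18024080 and 13922519 UMIs, 165 of 10580 genes were at least 2-fold higher and 2 lower. Myelin genes differed little, with 3 of 8 higher (Mbp, 0.13) and 5 lower around a median of -0.05, which was 0.0375 after thinning to 1000 UMIs.

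Other markers moved in oligodendrocytes too. Reactive astroglia genes C4b (1.74) and Serpina3n (1.54) were among 5 of 7 higher, dissociation stress genes had 10 of 14 higher and 3 lower (Fos, 1.74; median 0.72), and all 4 haemoglobin genes were lower (Hbb-bs, 57.3 against 725 CPM). As free RNA, the microglial gene C1qa stood at 46.3 against 10.4 CPM and Jchain at 154 against 51.9, and 9 of 10 T cell receptor complex genes were higher (Cd3e, 14.8 against 3.16 CPM). Within the class, cluster 11 held 604 cells of the anti-PD-1 library and 58 of the anti-TIGIT library. Its 10 leading genes included Serpina3n, C4b and the interferon-induced Iigp1 and Igtp. The 5 genes with the largest ratios upward were not seen in all oligodendrocytes. Without thinning, their detection ran from 13.4% and 0.209% of cells (Gbp2) to 45.1% and 5.08% (H2-T23). The interferon gamma list's median was 3.21 among Xist-positive cells and 2.68 among cells with Y-linked transcripts.

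OPCs of the anti-PD-1 library also carried more interferon response transcripts, together with those of cell cycle genes. The median ratio over all genes was shifted by -0.12 in this class, and values are given relative to it. Of 16 interferon gamma response and MHC genes 14 were higher, with a median of 1.71 (1.53 to 1.88), and of 11 type I interferon response genes 8 were higher (Isg15, 3.82, and Ifit3, 3.18), with a median of 1.84 (1.53 to 2.19). All 12 cell cycle genes were higher, among them Ube2c, a mitotic ubiquitin ligase component (2.04, 1.03 to 3.27), Mcm2 (1.95) and Stmn1 (0.56). Their median was 1.27 (1.06 to 1.85). Without the shift taken off, 9 of the 12 were higher and 3 had an interval holding 0. Reactive astroglia genes Serpina3n (1057 against 151 CPM, 2.92) and C4b (1.77) were higher and Gfap lower (-0.83), with 5 of 7 higher and a median of 1.70 (1.35 to 1.87). Of 8 myelin genes 5 were lower (Cnp, -1.03, and Cldn11, -1.17) and 3 higher (Mal, 1.43). The largest ratios upward were those of Fcgr2b, an inhibitory Fc receptor (6.09), Iigp1 (4.63), Gpnmb (3.89), Isg15 and Vgf. Vgf, a secreted neuropeptide precursor, had 233 and 0 counts and was 10.5-fold higher per CPM against a floor of 3 counts. Before the shift is taken off, its log2 interval began at 3.08. The largest downward were those of Chn2 (-3.59), Enpp6, a marker of newly forming oligodendrocytes (-3.59), Parvb (-3.86), Pik3r3 (-3.33) and Tmem163 (-3.04). Enpp6 was detected in only 2.98% and 10.2% of OPCs and Parvb in 2.84% and 7.63%, so these 2 ratios rest on few cells. Of 14 dissociation stress genes 9 were higher (Jun, 1.60; median 1.10), and C1qa stood at 33.7 against 5.15 CPM. Relative to the shift, 390 of 9462 genes were at least 2-fold higher and 220 lower, and 316 and 322 without it. The class held 705 and 118 cells. Its interferon gamma median was 3.02 among Xist-positive cells before the shift is taken off.

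Microglia of the anti-PD-1 library carried more class II MHC and interferon transcripts and fewer homeostatic ones. Here the median ratio over all genes was shifted by -0.25, and values are relative to it. All 16 interferon gamma response and MHC genes were higher, with a median of 1.43 (1.32 to 1.58). The class II genes H2-Eb1 (8287 against 1592 CPM, 2.63), H2-Aa (2.44) and Cd74 (2.47) led, with the T cell chemokine Cxcl9 at 2.38 and B2m at 0.57. All 10 homeostatic microglia genes were lower, with a median of -0.61 (-0.69 to -0.58): P2ry12, a purine receptor of resting microglia, stood at 462 against 1328 CPM (-1.28), Siglech at -1.45, Gpr34 at -1.22 and Tmem119 at -0.41. The list contains all 7 genes that named the class. Of 13 activated microglia genes 10 were higher (Cst7, 2.41, Itgax, 1.35, and Apoe, 0.96) and 2 lower (Spp1, -0.73, and Trem2, -0.19), with a median of 0.96 (0.69 to 0.98). Among type I interferon genes 10 of 11 were higher (Irf7, 1.61), with a median of 1.12 (0.95 to 1.22), and among 11 myeloid inflammation genes 8 were higher (Il1b, 1.66) and 3 lower (Nfkbia, -0.75). Cd274 stood at 181 against 45.9 CPM (2.22). Ccl5, at 2279 against 361 CPM, lay below 25% of its level in CD8 T cells and can be free RNA.

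The largest ratios upward in microglia were those of Il1rn, the interleukin 1 receptor antagonist (4.47), Cfb, complement factor B (3.09), Slamf7 (2.86), H2-Eb1 and Apoc1 (2.81), and downward those of Csmd3 (-2.93), Fcrls (-2.67), Adamts1 (-2.57), Serpinf1 (-2.48) and Hpgd (-2.22). Of 14 dissociation stress genes 9 were lower (Hspa1b, -2.08) and 4 higher, with a median of -0.16, and without the shift taken off 11 were lower and 1 higher, with a median of -0.41. Relative to the shift 261 of 9092 genes were at least 2-fold higher and 94 lower, and without it 155 and 243. Median depth was 7400 UMIs in the anti-PD-1 library and 3970 in the anti-TIGIT library, and the class lay mostly in different clusters: cluster 5 held 1015 and 79 cells and cluster 19 held 157 and 280. Without the shift taken off, the interferon gamma median was 2.66 among Xist-positive cells and 0.95 among cells with Y-linked transcripts, against 1.18 over all.

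**Figure D4:**
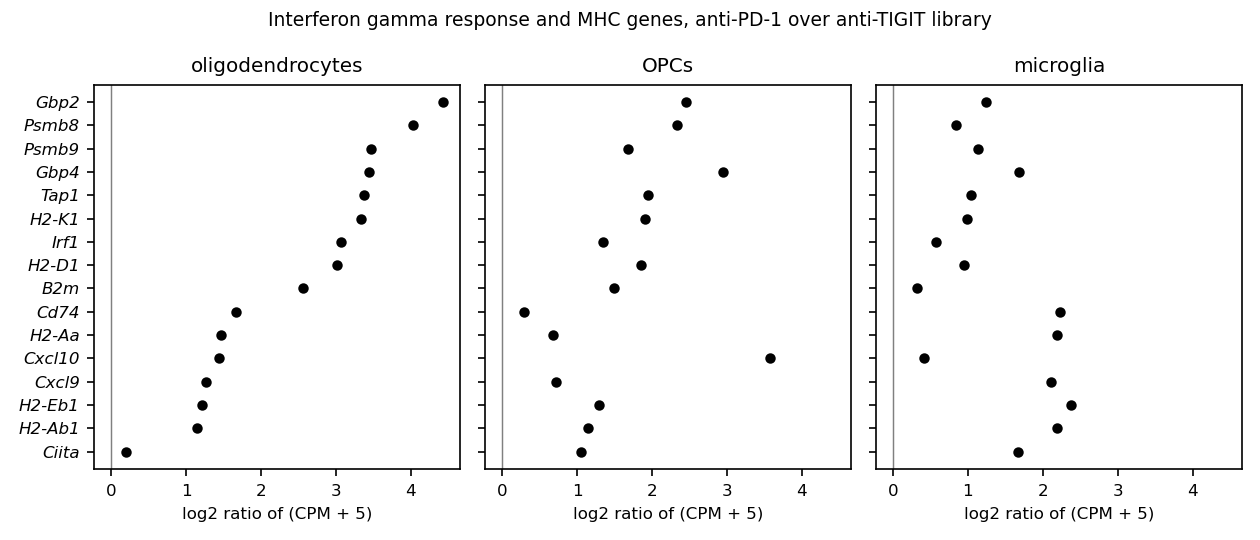
Log2 ratio of (CPM + 5), anti-PD-1 over anti-TIGIT, of the 16 interferon gamma response and MHC genes in oligodendrocytes, OPCs and microglia, a point per gene, without subtracting the shift of all genes. The medians were 2.79, 1.59 and 1.18.

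Regulatory T cells differed in receptors and cytokines but less than CD8 T cells in the genes the antibodies target. The values are over all cells of the class. Of its sex-called cells 32.8% were Xist-positive in the anti-PD-1 library and 0 of 42 in the anti-TIGIT library, so sex is not held equal. Pdcd1 stood at 498 against 269 CPM (0.89, 0.57 to 1.22) and Tigit at 934 against 832 (0.17, -0.02 to 0.36), an interval that holds 0. Of 10 inhibitory receptor genes 5 were higher, among them Havcr2 (1.57) and Lag3 (0.56), and 5 had an interval holding 0, with a median of 0.57 (0.27 to 0.84). Il10, a cytokine that restrains inflammation, was lower, at 138 against 325 CPM (-1.24, -1.56 to -0.90), while Ccl5 (1.24), Ccl4 (1.26) and the costimulatory receptor Tnfrsf9 (1.02) were higher. Xcl1 was higher too (171 against 18.8 CPM), but lay below 25% of its level in NK cells and can be free RNA. Cytotoxic genes Klrd1 (4.47) and Nkg7 (1.15) were among 5 of 10 higher, with a median of 0.63 (0.37 to 1.02), and interferon gamma response and MHC genes had a median of -0.11 (-0.26 to -0.01). Pdcd1, Ccl5, Klrd1 and Nkg7 are also leading markers of the exhausted-like CD8 T cell cluster, so some of their transcripts here can come from those cells. The largest ratios upward were those of Tff1 (228 and 0 counts), Klrd1, Camk2b (3.71), Eif3j2 (69 and 0 counts) and Alg9 (3.39). Against a floor of 3 counts Tff1 was 10.4-fold and Eif3j2 3.13-fold higher, and their log2 intervals began at 3.06 and 1.31. The largest downward were those of Tmtc2 (-1.58), Filip1l (-1.43), Rcn2 (-1.51), Cpm (-1.51) and Ern1 (-1.48). After thinning to 1000 UMIs Eif3j2 turned to -0.14. The plasma cell gene Jchain stood at 833 against 178 CPM in these cells.

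Cd274 was higher in both border macrophages and cDC2. In border macrophages Cd274 stood at 87.3 against 19.7 CPM (2.15), the acute phase gene Saa3 at 651 against 131 (2.32), Ccl8 at 748 against 180 (2.05), and Serpina3f (2.42) and Frmpd4 (2.13) were the other leading genes. Emp1 (-1.86), Tmtc2 (-1.78), Ccl9 (-1.53), Bmp2 (-1.84) and the neutrophil chemokine Cxcl2 (524 against 1466 CPM, -1.49) were lowest. The mix of clusters in border macrophages differed between the libraries. Cluster 1, with Saa3, Ccl8 and Cxcl2 among its 10 leading genes, held 559 and 765 cells. Cluster 15, led by Lyve1, held 129 and 418, and cluster 30 held 53 and 64. Of 16 interferon gamma response and MHC genes 15 were higher (median 0.43), of 9 glycolysis and hypoxia genes 8 were higher (0.68) and of 11 myeloid inflammation genes 6 were lower and 4 higher (-0.28), while of 14 dissociation stress genes 11 were lower and 2 higher (-0.14). In cDC2 the leading genes were Plet1 (2.72), the adhesion molecule gene Cdh1 (2.65), Cd274 (151 against 48.5 CPM, 1.63), P2ry14 (1.97) and Ccl17, a chemokine for T helper cells (1.51), and the lowest were Emp1 (-1.74), Phlda1 (-1.65), Ccl9 (-1.58), Stxbp6 (-1.64) and Tlr2 (-1.43). Of 11 myeloid inflammation genes in cDC2 9 were lower (-0.46), as were 11 of 14 dissociation stress genes (-0.20). Their interferon gamma list had 8 of 16 higher and 4 lower, and its median of 0.15 turned to -0.00597 after thinning and -0.0359 at a resolution of 0.5. As markers of T cells in these myeloid classes, all 10 T cell receptor complex genes were higher in both, with medians of 1.44 and 1.47, and all 4 haemoglobin genes were lower in border macrophages (median -4.38).

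Fibroblasts of the anti-PD-1 library had more transcripts of Ptgds, a prostaglandin synthase of the meninges (4546 against 666 CPM, 2.77), Prg4 (3.03), Dmkn (4.78), and of the skin genes Krtdap (3.84) and Sbsn (3.29). Tmtc2 (-2.22), Zfp804b (-1.95), Pgm5 (-1.87), Jarid2 (-1.66) and Ifit3b (-1.60) were lowest, although Ifit3b stood at 0.27 among Xist-positive cells. Of 16 interferon gamma response and MHC genes 13 were higher (median 1.07), while 6 of 11 type I interferon genes were lower (-0.63) and 8 of 11 cell cycle genes were lower (-1.22). Of 14 dissociation stress genes 9 were lower and none higher (-0.40). Markers of other cells were higher in fibroblasts too, with Igkc at 663 against 16.7 CPM, Jchain at 804 against 48.2 and 7 of 9 T cell receptor complex genes higher (1.16). In plasma cells all genes were shifted by 0.15, and relative to that the leading genes were Cep85 (2.79), Camk2b (1.48), Cox6a2 (1.60), Reln (2.04) and Galnt11 (1.41), and the lowest Prg2, an eosinophil granule gene (-4.26), Cxcl10 (-2.51), Tex14 (-1.36), Ly6k (-1.47) and Filip1l (-1.07). Among plasma cells 49 of 7449 genes were then at least 2-fold higher and 8 lower, against 71 and 6 unshifted, and 9 of 10 T cell receptor complex genes were higher (median 0.67). Sex was not held equal here, with 45.8% and 5.47% of sex-called plasma cells Xist-positive.

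B cells, NK cells and T cluster 3, a cluster of T cells given no further name, held the fewest cells compared. In B cells the leading genes were Upp1 (3.09), Apoc2 (2.48), Slc25a33 (2.72), Slc15a2 (2.05) and Camk2b (1.94), and the lowest Agbl1 (-6.59), Cacna1e (-2.69), Satb1 (-2.56), Foxp1, a transcription factor of resting lymphocytes (108 against 432 CPM, -2.01), and Cd55 (-1.86). Of 9 type I interferon genes in B cells 4 were higher (median 0.61). Lists of other cells moved too, with 4 of 7 myeloid inflammation genes higher (0.95) and 3 of 8 myelin genes (0.41). The microglial gene C1qa was lower there, at 85.9 against 134 CPM. In NK cells Nt5e (3.25), the granzyme gene Gzmc (2.90), Cxcl10 (1.84), Camk4 (1.79) and Plac8 (1.71) were highest and Rab27b (-1.49), Ankrd10 (-1.5001), Aff3 (-1.41), Klf12 (-1.29) and Filip1l (-1.18) lowest. Gzmc was detected in only 5.77% and 3.68% of NK cells, so its ratio rests on few cells. Of 14 interferon gamma response and MHC genes in NK cells 8 were higher (0.34). Microglial and macrophage markers were higher in NK cells as well, with Apoe at 282 against 30.04 CPM and C1qb at 111 against 12.5, and Cd74, which is in that list, stood at 601 against 200.2. Haemoglobin transcripts were also higher there in the anti-PD-1 library (Hbb-bs, 7588 against 67.6 CPM). In T cluster 3 Camk2b (5.94), Tnc (3.06), Sostdc1 (2.61), Art2b (2.47) and Slc15a2 (2.18) were highest and Ipo5 (-1.48), Snhg6 (-1.45), Slc7a5 (-1.39), Il18rap (-1.34) and Filip1l (-1.31) lowest. The inhibitory receptor median of T cluster 3 was 0.17 (-0.06 to 0.33), with 3 of 9 higher and 2 lower, and Hbb-bs stood at 700 against 48.8 CPM. Of the sex-called cells of T cluster 3, 50.5% were Xist-positive in the anti-PD-1 library and 0 of 71 in the anti-TIGIT library.

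Transcripts that tell the sexes apart showed that both pools held male and female cells. Xist, which silences the inactive X chromosome, was detected without Y-linked transcripts in 3079 cells of the anti-PD-1 library and 1496 of the anti-TIGIT library, and Y-linked transcripts without Xist in 3396 and 2474, so that 47.6% (46.3 to 48.8) and 37.7% (36.2 to 39.2) of sex-called cells were Xist-positive. Glia were mixed in both, with 40.9% and 43.5% Xist-positive among oligodendrocytes and 45.5% and 54.7% among microglia. Several T cell groups of the anti-TIGIT library held no Xist-positive cell among those called by sex. There, 0 of 42 regulatory T cells were Xist-positive, which allows up to 8.41%, as were 0 of 71 in T cluster 3 (up to 5.06%). Among exhausted-like CD8 T cells it was 0 of 14 (up to 23.2%). The shares in the anti-PD-1 library were 32.8%, 50.5% and 67.6%. Other T cell groups held some: the Xist-positive share was 30.7% in the Ly6c2/Gzmk cluster of the anti-TIGIT library and 19.05% in unnamed T cells, against 51.8% and 44.0% in the anti-PD-1 library. Plasma cells were Xist-positive in 5.47% (2.23 to 10.9) of the anti-TIGIT library and 45.8% (40.0 to 51.6) of the anti-PD-1 library. In CD8 T cells the sex-linked list followed, with Xist at a log2 ratio of 1.17, Ddx3y at -1.13 and a median of -0.38. Both kinds of transcript were seen in 1.84% and 0.8003% of retained cells.

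**Figure D5:**
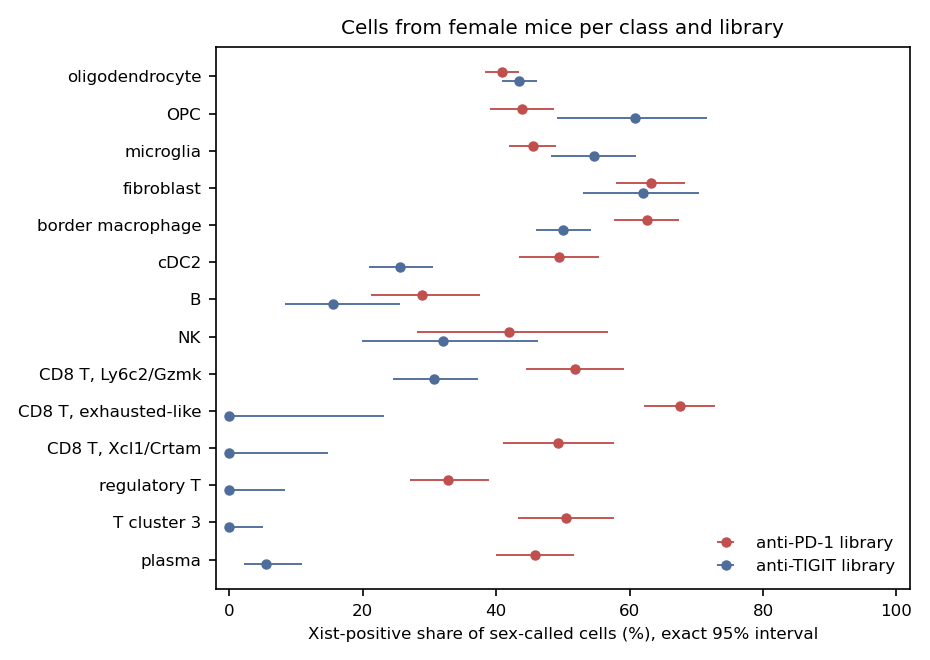
Xist-positive share of sex-called cells, in percent, per cell class and library, with exact 95% binomial intervals. Oligodendrocytes lie at 40.9% and 43.5%, while regulatory T cells lie at 32.8% in the anti-PD-1 library and 0 of 42 cells in the anti-TIGIT library.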

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

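The tests of unequal sexes, of depth in oligodendrocytes, of Xist detection, of clustering without list genes and of free RNA for each gene of the interferon gamma list were chosen after the results were seen. The test within the Ly6c2/Gzmk cluster was chosen after the cell clusters had been examined, but before its value was computed, as were the other tests here.

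Dissociation stress genes in CD8 T cells went opposite ways in the sexes, with a median log2 ratio of 0.75 (0.57 to 0.99) in Xist-positive cells and -0.29 (-0.42 to -0.03) in cells with Y-linked transcripts. The difference between the sexes was not tested, and the cells differ in cluster too, since all 65 Xist-positive CD8 T cells of the anti-TIGIT library lay in the Ly6c2/Gzmk cluster. Outside the compared classes, a cluster with the pituitary hormone genes Cga and Tshb held 13 cells of the anti-PD-1 library and 45 of the anti-TIGIT library, and a cluster with the hypothalamic peptide genes Avp, Oxt and Pomc held 61 and 26. Both are a signal in cells that no comparison used.

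Inhibitory receptor genes were higher in CD8 T cells of the anti-PD-1 library, with a median log2 ratio of 1.02. Thinning every cell to 1000 UMIs gave 1.30, so the larger weight of deeper cells in the sums does not account for it. Thinning keeps the expected makeup of each cell, so other effects of depth stay open. For Pdcd1, free RNA does not account for the difference of 608 CPM. The highest Pdcd1 level in a compared class outside lymphocytes, 28.6 CPM in cDC2, was 4.70% of it. Unequal numbers of male and female cells do not account for the list's median, since the lower of the medians within a sex was 1.06. A shift between CD8 T cell clusters stays open, because within the Ly6c2/Gzmk cluster the median was 0.46 (0.21 to 0.73), against 0.51, the bound written before that value was computed, and 0.25 (0.16 to 0.73) when clustered without list genes. The treatment and differences between the pools of mice are further explanations, untested with 1 library per group. They cannot be told apart from each other or from the Cell Ranger version.

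Interferon gamma response and MHC genes were higher in OPCs and oligodendrocytes of the anti-PD-1 library. Free RNA from microglia does not account for most of it: B2m was higher by 1001 CPM in OPCs and 1165 in oligodendrocytes against 79.1 and 94.0 for C1qa, C1qb and C1qc together, which is 86.8 and 85.0 times the ratio of 0.146 in microglia. Of the 16 genes, 13 in OPCs and 11 in oligodendrocytes lay above 5 times their ratio. For others, such as Cd74 at 1.09 and 1.60 times, free RNA from microglia stays open. Free RNA from other cells, such as T cells and plasma cells, was not tested and stays open for all 16 genes. The plasma cell gene Jchain was higher in oligodendrocytes (154 against 51.9 CPM) and lower in OPCs (970 against 1814 CPM). Thinning to 1000 UMIs gave medians of 1.99 and 2.86, so the larger weight of deeper cells does not account for the higher list medians. Other effects of depth stay open, since thinning keeps the expected makeup of each cell. The treatment, differences between the pools of mice, a shift between oligodendrocyte clusters and the Cell Ranger version stay open as untested.

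Regulatory T cells, T cluster 3, exhausted-like CD8 T cells and plasma cells of the anti-TIGIT library held 551 cells, of which 255 were called by sex. Of these 255, 248 carried Y-linked transcripts and 2.75% (1.11 to 5.57) were Xist-positive. Another 287 cells showed neither kind of transcript and 9 showed both. Undetectable Xist does not account for it, since 50% (47.0 to 53.0) of 1066 such cells were Xist-positive in the anti-PD-1 library. Few contributing animals stay open: the leading beta segment, Trbv16, was carried by 35.7% (12.8 to 64.9) of 14 male exhausted-like cells, and a share below 50% was set beforehand as leaving the number of animals open. The sex of the animals in each pool, which the labels do not give, is open as well.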

How the results depend on the processing

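The alternatives within each sex, within the Ly6c2/Gzmk cluster and without list genes were chosen after the cell clusters had been examined, and all others before the data were opened. The bound for the Ly6c2/Gzmk cluster was written before its value was computed. Leaving out replicates was not possible, since each group has 1 library. No paired analysis was possible because the labels pair no mice or libraries. Genes under 10 counts and classes under 10 cells in an alternative were left out of it.

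Among the main results, settings chosen beforehand left 112 values within their interval or size and moved 37, none of which turned. Those chosen afterwards left 21, moved 38 and turned 2. Of the other values, settings chosen beforehand left 1276, moved 182 and turned 7, and those chosen afterwards left 238, moved 203 and turned 11. Limits of 500 genes with 5% mitochondrial UMIs or of 20% moved none of the main results they reached. A minimum of 1 count and no free RNA filter each applied to only 2 main values, both counts of genes, and moved neither. A count was called moved if it changed by more than 1.5 times. Without the filter 8 of the 12 genes named upward in CD8 T cells stayed, which lies at that bound, and 10 of the 12 downward. The other main results did not use the filter, so this says nothing on them. Except where the construction of an alternative shows it, as for fewer genes or other pseudocounts, the cause of a move was not tested.

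With CD8 T cells gated by UMIs, their share differed by 5.12 points, Pdcd1 had a log2 ratio of 1.54, Tigit 1.16, the inhibitory receptor median was 0.80 and the cytotoxic median -0.31. The type I interferon median turned to -0.29, and 371 genes were at least 2-fold higher and 48 lower.

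At resolution 0.5 the CD8 T cell share differed by 0.210 points and the regulatory T cell share by 3.42. In CD8 T cells Pdcd1 stood at 1.93, the exhaustion programme at 0.65, progenitor and memory genes at -0.48, cytotoxic genes at -0.0142, and type I interferon genes turned to -0.12. The interferon gamma median of cDC2 turned to -0.0359. At resolution 2.0 progenitor and memory genes stood at -0.48 and the interferon gamma median of OPCs at 2.25.

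With every cell thinned to 1000 UMIs before summing, Pdcd1 stood at 2.15, Tigit at 1.58, inhibitory receptors at 1.30 and cytotoxic genes at -0.27 in CD8 T cells. Interferon gamma genes stood at 1.99 in OPCs and 2.86 in oligodendrocytes, and homeostatic genes at -0.78 in microglia. Eif3j2 in regulatory T cells turned to -0.14, the interferon gamma median of cDC2 to -0.00597 and myelin in oligodendrocytes to 0.0375. Scaling by the median ratio gave 1.43 for interferon gamma genes and -0.61 for homeostatic genes in microglia. Without doublet removal, interferon gamma genes stood at 2.66 in oligodendrocytes and type I interferon genes in CD8 T cells turned to -0.14.

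The number of CD8 T cell genes at least 2-fold higher and lower was 54 and 15 with at least 200 counts, 210 and 58 with a pseudocount of 1 CPM, and 31 and 8 with a pseudocount of 20 CPM. The Pdcd1-positive and Tigit-positive shares differed by 23.3 and 17.4 points after thinning to 500 UMIs, 45.3 and 33.3 after thinning to 2000 and 47.9 and 36.9 without thinning, since deeper cells show more genes.

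Within the Ly6c2/Gzmk cluster, Pdcd1 stood at 1.22, Tigit at 0.68, inhibitory receptors at 0.46 and cytotoxic genes at -0.27, with 10 genes higher and 14 lower. The Pdcd1-positive share differed by 9.97 points and the Tigit-positive share by 5.30. The exhaustion programme turned to -0.0307, progenitor and memory genes to 0.0831, cytokines and chemokines to -0.30, Ccl3 to -0.37, tissue residency to -0.16, glioma-supporting signals to -0.12 and activated microglia genes to -0.19. With T cells clustered without list genes, progenitor and memory genes stood at -0.47.

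Among Xist-positive cells, shares differed by 8.19 points for CD8 T cells, 2.80 for microglia and -19.8 for oligodendrocytes, and the share of B cells turned to 0.400, with an interval holding 0. The exhausted-like share differed by 55.2 points, the Pdcd1-positive share by 51.4 and the Tigit-positive share by 38.9. Pdcd1 stood at 4.39, Tigit at 3.36, inhibitory receptors at 2.28, the exhaustion programme at 1.51 and cytotoxic genes at -0.29, with 492 genes higher and 85 lower. Interferon gamma genes stood at 3.02 in OPCs, 2.66 in microglia and 3.21 in oligodendrocytes, and homeostatic genes at -0.97. Spock2 turned to -0.0857 and myelin to -0.13 in CD8 T cells, and Ifit3b to 0.27 in fibroblasts.

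Among cells with Y-linked transcripts, shares differed by 0.513 points for CD8 T cells, 8.29 for microglia, -7.62 for border macrophages, -5.23 for oligodendrocytes and 3.37 for regulatory T cells. The shares of plasma cells and B cells turned, to -0.179 and 0.0523, with intervals holding 0. The exhausted-like share differed by 30.2 points and the Pdcd1-positive share by 27.5. Pdcd1 stood at 1.44, Tigit at 1.17, homeostatic genes at -0.77, and interferon gamma genes at 0.95 in microglia and 2.68 in oligodendrocytes.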

Other observations

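Cd274, which encodes the PD-1 ligand PD-L1, was higher in the anti-PD-1 library in 10 of 12 classes. Its log2 ratio was 4.44 in oligodendrocytes, 2.15 in border macrophages and 1.63 in cDC2, and its intervals held 0 in B cells (-0.02) and regulatory T cells (-0.19). Cxcl13, which draws B cells and follicular T cells, was higher in microglia at 4577 against 2024 CPM and border macrophages at 1543 against 451 CPM. The value of Cxcl13 was higher in 9 other classes as well, but below 25% of its level in microglia, such as 79.0 against 21.7 CPM in CD8 T cells, so there it can be free RNA. Other genes moved alike in every class: of 1977 genes with enough counts in all 12 classes, 5 were higher in each, among them Fth1 (0.13 to 1.10), the ferritin heavy chain, and the respiratory chain gene Cox7c (0.28 to 0.73), and 6 were lower in each, among them Filip1l (-1.43 to -0.69) and Jarid2 (-1.66 to -0.59). Tmtc2 was lower in 11 of the 12 classes and higher in 0. Camk2b was higher in 10 and lower in 0. Both are thus not particular to the classes in which they were among the leading genes.

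Segments of the T cell receptor were uneven in exhausted-like CD8 T cells. Trbv3 led in the anti-PD-1 library, in 26.4% (22.9 to 30.2) of 583 cells and in 42.0% (35.2 to 49.1) of the 207 that were Xist-positive, while Trbv16 led in the anti-TIGIT library, in 34.1% (20.5 to 49.9) of 44 cells. In the Ly6c2/Gzmk cluster the leading segments were Trbv13-3 at 14.1% (10.8 to 18.04) and Trbv1 at 11.4% (8.57 to 14.7). Regulatory T cells shared their leading segment, Trbv13-3, at 20.96% (17.4 to 24.9) and 28.7% (20.1 to 38.6). Plasma cells most often carried Igha as leading heavy chain, in 51.0% and 54.8% of cells, followed by Ighg2c in 28.6% and 27.8%.

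In the cluster with Cga and Tshb, Chga stood at 49684 and 52825 CPM, while Prl and Gh had 0 counts in both libraries. In the cluster with Avp, Oxt and Pomc, Avp stood at 2348 and 59850 CPM, from 7 and 8 cells, and Npy at 3266 and 6.04 CPM. Bpifa1, an airway gene, had 29681 counts in a cluster of 123 cells of the anti-PD-1 library, from 6 cells, and 0 counts in its 55 cells of the anti-TIGIT library. Over the whole libraries the haemoglobin gene Hbb-bs stood at 378 and 1082 CPM.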
